A study of Homo sapiens with 4 samples.

How the data were processed

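Gene expression was measured on Illumina HumanHT-12 v3 BeadChips, a one-colour array of oligonucleotide probes on beads, in H520 and LK2, 2 established cell lines of human lung squamous cell carcinoma. Per the labels, cells of each line received a pool of siRNAs against SOX2, which degrade its mRNA, or scrambled control siRNAs, and RNA was harvested 48 h later. Biotin-labelled cRNA was made from total RNA, per the labels' protocols. The 4 arrays form 4 groups of 1 array each, so no group has a replicate and the number of arrays limits the precision of every value.

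The values used here were the authors' processed log2 values for 48801 probes, as deposited in the series value table. The tool, background correction and centring behind them are not given in the sources used here. All 4 columns had a mean of 0.00475, as arrays do after quantile normalization. Their medians were 0.000149 for H520 control, 0.00118 for H520 SOX2 siRNA, 0.000493 for LK2 control and -0.000497 for LK2 SOX2 siRNA. Column medians lay near 0 and values ran from -6.68 to 6.59, so the values were taken as centred per probe. Probes with a large difference between the lines, such as that of SHISA2 (6.59 in LK2 control), still lay far from 0 on these arrays. The 2 H520 columns summed to 0, within 2e-06, at 10.9% of probes, and the other pairs of columns at 4.64 to 5.45% of probes. That pattern is what a median over a larger, even-sized set of arrays holding both lines would leave, but which arrays were in that set stays unknown. Centring cancels in every difference between arrays, and no signal level can be read from the values.

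A second table held linear scanner intensities in 4 value columns whose names match no label of any sample. These 4 columns were given to no sample and entered no result. They were read only to count them and to settle the log base: differences between pairs of log2 scanner columns were set against differences between pairs of processed columns. The best 2 matches had absolute correlations of 0.994 and 0.993 across probes and slopes of 0.896 and 1.06. A slope of 1 is what log2 values would give, against 0.693 for natural logs and 0.301 for log10. The direction of each difference comes from the sample named in each column of the processed table.

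Probes were named from the platform's annotation table. Of the 48801 probes, 28096 had 1 gene symbol, 13 had several and 20692 were not listed there, and only the first kind were named. Of the named probes, 28057 were matched by Entrez identifier to the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed updating. The files give no genome build for the probes, so no coordinates are printed. A gene's value was the mean of its probes, which gave 18852 genes, 6131 of them with more than 1 probe.

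The plan written before the data were examined was background correction and quantile normalization of the scanner intensities with an offset of 16, a filter on detection p-values and the brightest probe of each gene. None of these could be run on the processed values, and no detection p-values or bead-level errors were used here. The mean of a gene's probes was the written alternative to the brightest probe and became the main setting. Counts of calls per probe and per gene had both been seen when that was settled. Random gene lists were matched on the size of the difference between the lines in place of mean expression. The list test on the difference between lines was added after seeing the data.

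The siRNA contrast was tested with limma 3.58.1 in R 4.3.3, with cell line as a block, so that the 2 lines act as the replicates. The pairing by cell line comes from the labels. The fit had 1 residual degree of freedom per gene and 5.19 prior degrees of freedom from empirical Bayes moderation. Adjusted p-values are Benjamini-Hochberg values over all genes, with a threshold of 0.05, and tests were two-sided. The same fit gave the difference between the lines. The 1 residual of each gene is the difference between the siRNA responses of the 2 lines. Standard errors and p-values, also those of the line difference, therefore rest on that difference, moderated across genes. The labels do not say whether arrays came from separate experiments, so noise between arrays cannot be separated from it. Within a line there was no test, and genes were counted at 1.5-fold, with 2-fold as the alternative. Counts expected of independent lists were the product of the counts in each line over the number of genes.

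Gene lists were fixed before the data were examined: 24 lists with 600 genes, of which 548 were measured. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists, and again with an estimated correlation and with fry. With an estimated correlation camera uses only the 1 residual degree of freedom, so hardly any list can pass it. A failure there does not show that members are correlated. The fry test also draws on that 1 residual degree of freedom, so a list that fails it may still have moved. The lists were squamous basal markers, cornified differentiation, BMP signalling, SOX family and pluripotency, the 3q26-q29 neighbours of SOX2, S phase, G2/M phase, p53 targets, apoptosis regulators, epithelial adhesion, mesenchymal and EMT, lung adenocarcinoma and airway, neuroendocrine, immune cells, NRF2 targets, Wnt targets, Notch pathway, interferon response, NF-kB and cytokines, unfolded protein response, glycolysis and hypoxia, cholesterol synthesis, ribosomal proteins, and growth factor receptors. Per line, a list's median was placed among 10000 random lists of the same size, matched on 10 bins of the absolute difference between the lines. That percentile describes these arrays and is not a test.

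The rule for named genes was also fixed before the data were examined. It took SOX2, the 12 genes in each direction with the largest smaller change among genes moving the same way in both lines, and the 8 with the largest change per direction in each line. It also took the 5 genes with the largest opposite changes each way, the 10 with the largest significant difference between lines each way, and up to 4 members of each list with the largest mean absolute change. Members of lists in counts of 5 or fewer were named too. The part of the rule that bounds a fold at background could not be applied without detection p-values.

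The fit and list test were tested on simulated data with the variances of the shared fit over 18852 genes, 200 of them changed. Of the genes changed by a log2 value of 1, 98% were called, and of those changed by 2, 100% were called. Each simulated change was the same in both lines. The 200 planted changes, at log2 values of 1 or 2, also ease the Benjamini-Hochberg threshold for every gene. These shares therefore do not carry over to the arrays. There CRABP2, at 1.02 in H520 and 1.03 in LK2, had a limma adjusted p of 0.0752, so an uncalled gene may still have changed. There were 14 unchanged genes called. A simulated list shifted by 0.3 had a camera p of 4.21e-14 and an unchanged list had 0.527. Simulated genes were independent and only 1 unchanged list was drawn. The simulation therefore cannot show how often lists of correlated genes are called falsely at the preset correlation. Alternatives were the variance prior with a trend, a minimum fold of 1.2 by limma's treat, no block for cell line, and each line alone. Added after seeing the data were the probe with the largest difference between lines, array medians set to 0, only genes above the median absolute difference between lines, and every probe tested separately. Figures were drawn with matplotlib 3.10.9.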

Results

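The series holds 4 arrays from 2 lung squamous cell carcinoma lines, H520 and LK2, each with control siRNA and with siRNA against SOX2, a transcription factor gene of the 3q region often amplified in this cancer. RNA was taken at 48 h. There was 1 array per group, with 48801 probes and 18852 named genes on each. The design asks which transcripts differ when SOX2 is depleted and whether the lines respond alike. Changes are log2 differences, SOX2 siRNA minus control siRNA. Within a line they have no replicate check. An error given after ± is the standard error of the limma fit over both lines. It grows with the difference between the siRNA responses of the lines.

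SOX2 itself was lower with its siRNA in both lines. In H520 its log2 change was -0.66, and its 2 probes stood at 63.2% and 63.8% of the control array. In LK2 the change was -2.11, with 26.9% and 19.9% remaining by the same probes. Across both lines the change was -1.38 ± 0.31, with a limma adjusted p of 0.33, so SOX2 did not pass the test over all genes. SOX2 fell by unequal amounts in the 2 lines, which raised that error. With probes tested separately by limma, 1 of its 2 probes passed (-0.66 and -1.89, adjusted p = 0.0462). Knockdown on these arrays was therefore smaller in H520 than in LK2, a difference that was not tested. For comparison, the 2 probes of a gene had an SD of 0.18 in H520 and 0.21 in LK2 over 3934 genes.

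HMOX1, the inducible haem oxygenase, rose in the lines together, by 2.12 ± 0.12 on the log2 scale (limma, adjusted p = 0.0296). It was 4.87-fold higher in H520 and 3.87-fold higher in LK2. The keratin gene KRT23 was higher by 1.85 in H520 and 2.96 in LK2, the efflux transporter gene ABCC3 by 1.23 and 1.78, and the homeobox gene DLX3 by 1.14 and 1.70. CRABP2, which binds retinoic acid in the cell, was higher by 1.02 and 1.03, and SFN, the 14-3-3 sigma gene, by 0.99 and 1.76. The other named genes higher in both lines were FHOD3 (1.27 and 1.10), ADAMTSL2 (1.05 and 1.75), FAM107B (1.04 and 1.79), MAP3K8 (1.78 and 0.99) and MTSS1 (0.92 and 1.21). DKK1, a secreted Wnt antagonist, was higher by 1.01 and 1.05, although its probes disagreed, with 1.61 and 1.84 by one and 0.41 and 0.25 by the other.

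SOX21, another SOX family transcription factor, was lower by -1.66 in H520 and -1.21 in LK2. IL13RA1, a receptor subunit for interleukin signalling, was at -1.41 and -2.09. The calcium channel gene CACNA1E was at -1.35 and -1.33, the protocadherin gene PCDH19 at -1.19 and -1.39, the T-box gene TBX2 at -1.26 and -1.08, and the Wnt receptor gene FZD1 at -0.98 and -2.06. Further named genes lower in both were TMEM158 (-1.72 and -1.14), C6orf15 (-1.05 and -3.63), THEMIS (-1.05 and -1.22), MLEC (-1.03 and -1.51), FBN2 (-0.99 and -1.31) and PDLIM1 (-1.31 and -0.98).

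Of the 18852 genes tested by limma, 1 was higher (HMOX1) and 0 were lower at the adjusted threshold, while 1584 had an unadjusted p under 0.05 against 943 expected by chance. At an adjusted p under 0.1, a threshold added after seeing the data, 10 genes were higher and 15 lower. The other named genes higher or lower in both lines had adjusted p-values from 0.0752 (FHOD3, CRABP2, DKK1, IL13RA1, CACNA1E, SOX21, PCDH19, TBX2 and THEMIS) to 0.332 (C6orf15). The count of calls depended on the setting: 10 higher and 12 lower with a variance trend, 20 and 22 with 1 probe per gene, 93 and 84 over separate probes, and 0 higher when the test was limited to genes above the median line difference. Without the block for cell line, 0 genes passed, with 148 at an unadjusted p under 0.05.

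**Figure D1:**
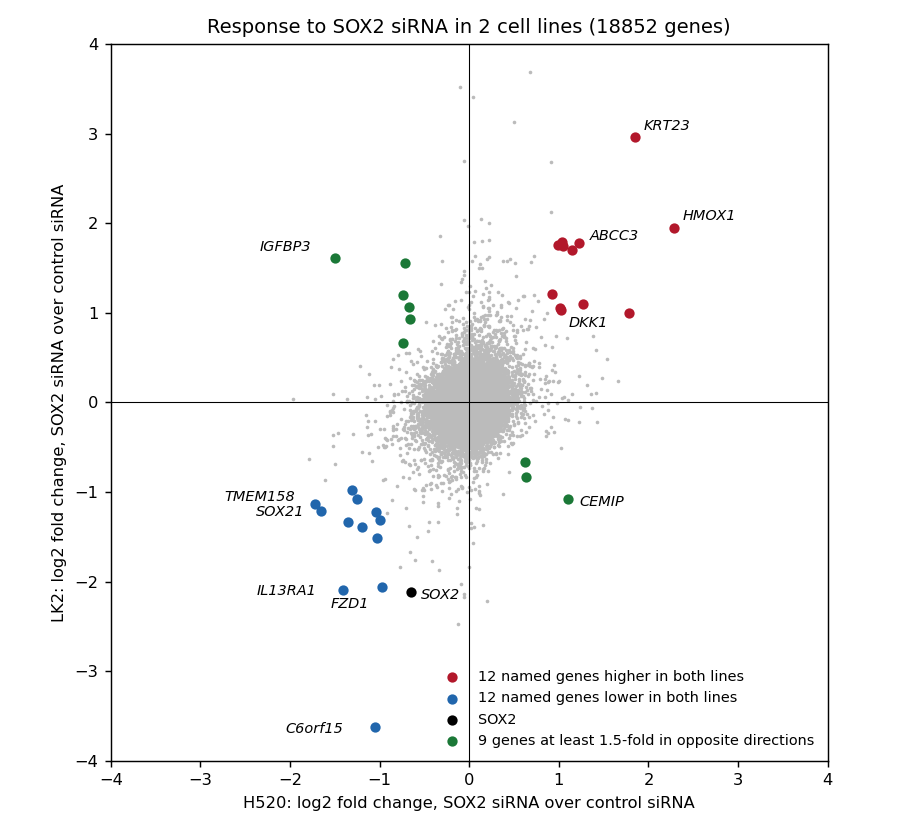
Log2 fold change (SOX2 siRNA over control siRNA) of 18852 genes in H520, on the horizontal axis, against LK2, on the vertical axis, each point being 1 gene on 1 array pair per line. HMOX1 lies at 2.28 and 1.95, SOX2 at -0.66 and -2.11, and IGFBP3 at -1.50 and 1.61.

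Genes that differed by at least 1.5-fold in both lines mostly did so in the same direction. There were 42 genes higher in both lines and 41 lower in both, where independent lists would share 2.89 and 2.62. In opposite directions there were 9, where 5.80 would be shared. The expected counts run over all 18852 genes with no detection filter, so they may be too low if many genes gave no signal. At 2-fold, 9 genes were higher and 9 lower in both lines, and 2 (IGFBP3 and CEMIP) went opposite ways. Across all 18852 genes, the log2 changes of the lines correlated with a Pearson r of 0.232 and a Spearman rho of 0.146. These are correlations across genes, which are not independent replicates, and the lines share no control array.

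In H520 alone, 152 genes were at least 1.5-fold higher and 201 lower. The largest increases beyond HMOX1, KRT23 and MAP3K8 were PNPLA7 at 1.66, VASN at 1.54, the collagen gene COL6A3 at 1.49, ALPK2 at 1.43 and SYNGR4 at 1.42. The lowest were FSTL5 at -1.97, the growth factor carrier gene FGFBP1 at -1.79, TMEM158, SOX21, ENTPD3 at -1.61, NELL1 at -1.53, CSRP2 at -1.52 and the BMP antagonist gene SOSTDC1 at -1.52. At 2-fold the total was 70 genes. The SD of the log2 changes over genes was 0.212 in H520 and 0.26 in LK2, so equal folds are not equally rare in the lines.

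In LK2 alone, 358 genes were at least 1.5-fold higher and 246 lower. MYL10 was higher by 3.69, EFEMP1 by 3.52, the endothelin gene EDN3 by 3.40 and EDAR, the ectodysplasin receptor, by 3.13. KRT23 followed at 2.96, the histidine decarboxylase gene HDC at 2.70, ENTREP2 at 2.68 and the Wnt inhibitor gene APCDD1 at 2.13. The lowest were C6orf15 at -3.63, TRIM49D1 at -2.47, GEMIN4 at -2.22, CEACAM6 at -2.17, CAVIN2 at -2.14, SOX2, IL13RA1 and FZD1. At 2-fold the total was 146 genes. These values come from 1 pair of arrays, and several of these genes were near 0 in H520, such as EDN3 at 0.04, EFEMP1 at -0.10 and CEACAM6 at -0.06, with no test of the difference.

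Genes that moved opposite ways were led by IGFBP3, a binding protein of insulin-like growth factors, at -1.50 in H520 and 1.61 in LK2. The metallothionein genes MT2A and MT1G were at -0.74 and 1.19 and at -0.73 and 0.66. WIPI1 was at -0.72 and 1.56 and EXOG at -0.67 and 1.06. In the other direction were the hyaluronan-degrading CEMIP at 1.10 and -1.07, ERVMER34-1 at 0.63 and -0.83, the MAP kinase phosphatase DUSP6 at 0.63 and -0.66, ABHD17C at 1.03 and -0.50, and DSCC1 at 0.47 and -0.47.

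NRF2 targets, genes of antioxidant defence, rose as a list (camera adjusted p = 8.05e-07, but adjusted p = 0.697 with an estimated correlation). Of 21 measured members, 15 were higher in both lines and 0 lower in both, with medians of 0.19 in H520 and 0.16 in LK2. HMOX1 was called over all genes, and 2 members, HMOX1 and EPHX1 (0.42 and 0.96), when adjusted over the list alone. The cystine transporter gene SLC7A11 was at 0.15 and 1.07, while TXNRD1, thioredoxin reductase, was at -0.89 and 0.20. Wnt targets also rose (camera adjusted p = 0.000512, but adjusted p = 0.697 with an estimated correlation), with 8 of 19 members higher and 3 (SFRP1, FZD7 and ZNRF3) lower in both lines and medians of 0.10 and 0.18. APCDD1 (0.91 and 2.13), DKK1, SP5 (0.85 and 0.22) and NKD1 (0.72 and 0.32) led it. No Wnt member was called over all genes and 7 were when adjusted over the list alone, among them SFRP1 with lower values (-0.32 and -0.32). APCDD1, DKK1, NKD1, NOTUM and SFRP1 are known as inhibitors of Wnt signalling.

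Targets of p53 rose as a list (camera adjusted p = 0.00014, but 0.697 with an estimated correlation and 0.0633 without the block for cell line), with 12 of 22 members higher and 1 (CCNG1) lower in both lines and medians of 0.08 in H520 and 0.27 in LK2. Its members with the largest changes differed between lines: GDF15 was at 1.23 and 0.30, GADD45A at 0.84 and -0.13, SESN2 at -0.07 and 0.95, and TNFRSF10B at -0.52 and 0.39. The value of TNFRSF10B rests on 1 of its 3 probes, at -1.28 and 0.85, against -0.06 and 0.10 and -0.20 and 0.22 by the others. No member was called over all genes and 0 were when adjusted over the list alone. The BMP signalling list rose too (camera adjusted p = 0.0187, but 0.697 with an estimated correlation and 0.858 without the block), with 10 of 28 members higher and 6 lower in both lines and medians of 0.18 and 0.05. It holds BMP4, included from general knowledge of the study and not from the labels, so its direction is not independent evidence. BMP4 itself was at 0.22 and 0.13. The homeobox genes DLX3 and MSX1 (0.70 and 1.02) led the list, followed by ID3 (0.44 and -0.77) and HEY1 (0.86 and 0.29). In H520 the probes of HEY1 disagreed, at 1.46 and 0.26. Over all genes 0 members were called and 6 when adjusted over the list alone, which is not independent evidence either.

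Cell cycle genes fell as lists at the preset correlation, and their values were lower mainly in LK2. G2/M genes (camera adjusted p = 6.98e-07, but adjusted p = 0.697 with an estimated correlation) had medians of -0.06 in H520 and -0.30 in LK2, and 20 of 30 were lower in both lines and 0 higher in both. In LK2, 29 of the 30 were lower. The largest changes were in BUB1B (0.15 and -0.74), CCNA2 (-0.28 and -0.52), HMMR (-0.55 and -0.24, with -0.56 and 0.08 by its probes in LK2) and TTK (-0.28 and -0.45), and 0 members were called over all genes or when adjusted over the list alone. S phase genes (camera adjusted p = 1.73e-05, but adjusted p = 0.697 with an estimated correlation) had medians of -0.01 and -0.39, with 24 of 27 lower in LK2 and 14 lower in H520. The replication genes CDC45 (-0.50 and -0.97), RRM2 (-0.14 and -1.24), DTL (-0.14 and -1.17) and GINS2 (-0.30 and -0.99) led the list. Of these, 0 were called over all genes and 1, CDC45, when adjusted over the list alone. The estimated inter-gene correlation, on 1 residual degree of freedom, was 0.43 for G2/M and 0.59 for S phase genes, against the preset 0.01. Their p-values at the preset may therefore be too small. The difference between lines was not tested.

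Genes of glycolysis and hypoxia fell as a list (camera adjusted p = 0.000512, but adjusted p = 0.697 with an estimated correlation), with 17 of 25 lower and 4 (SLC2A1, PKM, VEGFA and EGLN3) higher in both lines and medians of -0.16 in H520 and -0.20 in LK2. PGAM1, a glycolytic enzyme gene, was at -0.54 and -0.46, BNIP3 at -0.38 and -0.52 and ANKRD37 at -0.43 and -0.29, while the glucose transporter gene SLC2A1 was at 0.25 and 0.39. Members called over all genes and adjusted over the list alone both numbered 0. Cholesterol synthesis genes also fell (camera adjusted p = 0.00187, but adjusted p = 0.697 with an estimated correlation), with 10 of 17 lower and 2 (HSD17B7 and SREBF2) higher in both lines and medians of -0.12 and -0.23. HMGCS1 was at -0.12 and -1.10, INSIG1 at -0.22 and -0.95, MVK at -0.30 and -0.65 and HSD17B7 at 0.37 and 0.83. Over all genes 0 were called and 3 when adjusted over the list alone: MVK, HSD17B7 and CYP51A1 (-0.60 and -0.33). By fry, 0 of the 24 lists passed, and the lowest adjusted p, 0.103, was that of NRF2 targets and of glycolysis and hypoxia. That test too had only 1 residual degree of freedom.

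**Figure D2:**
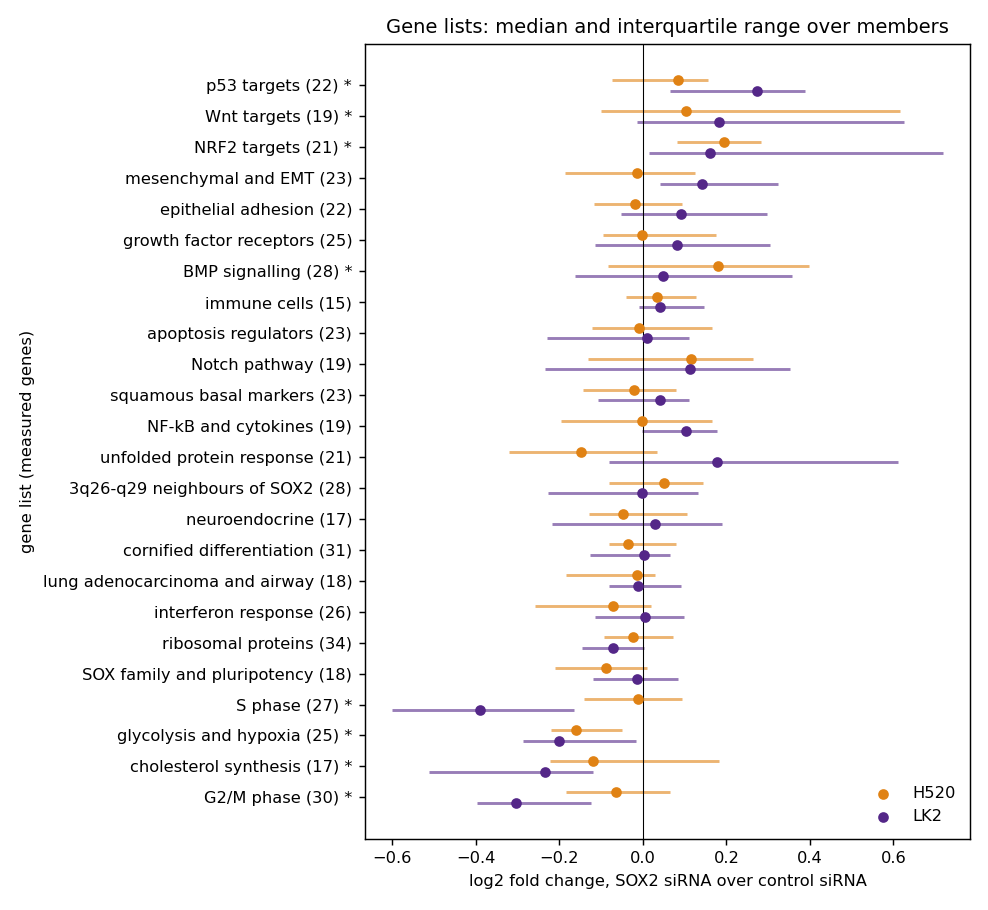
Median log2 fold change (point) and interquartile range over members (line) of the 24 gene lists in H520 (orange) and LK2 (purple), with the number of measured genes in parentheses and an asterisk at the 8 lists past camera's threshold at the preset correlation. S phase genes sit at a median of -0.01 in H520 and -0.39 in LK2, and NRF2 targets at 0.19 and 0.16.

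Lineage lists did not pass the test. Squamous basal markers had medians of -0.02 in H520 and 0.04 in LK2 (camera adjusted p = 0.826), with SFN highest, PERP at -0.80 and 0.10, CALML3 at 0.88 and 0.00, and DSP at 0.29 and -0.34. Cornified differentiation genes had medians of -0.04 and 0.00 (adjusted p = 0.849), with TGM3 at 0.73 and -0.21, EVPL at 0.28 and 0.34, CRNN at 0.13 and -0.44 and KRT10 at -0.21 and 0.24. The SOX family and pluripotency list had medians of -0.09 and -0.01 (adjusted p = 0.172), and beyond SOX21 and SOX2 its largest changes were in SOX15 (-0.57 and 0.16) and SOX12 (0.43 and -0.13). The 3q26-q29 neighbours of SOX2 had medians of 0.05 and 0.00 (adjusted p = 0.849), with DNAJC19 at -0.42 and 0.57, BCL6 at -0.32 and -0.58, ABCC5 at 0.49 and 0.29 (0.61, 0.35 and -0.09 by its 3 probes in LK2) and PRKCI at 0.52 and 0.19. Lung adenocarcinoma and airway genes had medians of -0.01 and -0.01 (adjusted p = 0.249), with TFF3 at -0.43 and -0.97, FOXA1 at -0.42 and -0.64, FOXA2 at 0.03 and -0.51 (-1.39, -0.23 and 0.10 by its 3 probes in LK2) and NKX2-1 at -0.29 and -0.10. Neuroendocrine genes had medians of -0.05 and 0.03 (adjusted p = 0.653), with CHGB at -0.81 and -0.24, INSM1 at -0.76 and -0.18, DDC at -0.62 and 0.19 and UCHL1 at 0.11 and 0.64. Immune cell markers, included as a check for other cells, had medians of 0.03 and 0.04 (adjusted p = 0.26), with CD68 at 0.29 and 0.40 (0.84, -0.07 and 0.44 by its 3 probes in LK2), TYROBP at -0.25 and 0.15, MS4A1 at 0.16 and -0.24 and CD14 at 0.21 and 0.06. Adjusted over the list alone, SFN was called among squamous markers, SOX21 and SOX2 in the SOX family, and TFF3 and FOXA1 among airway genes, and 0 in the other lineage lists. None of these lists had a member called over all genes.

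Epithelial adhesion genes had medians of -0.02 in H520 and 0.09 in LK2 (camera adjusted p = 0.353), with ST14 at 0.00 and 1.29, ELF3 at -0.32 and -0.65, KRT19 at -0.48 and -0.41 and MUC1 at 0.40 and 0.28. Mesenchymal and EMT genes had medians of -0.01 and 0.14 (adjusted p = 0.0708), and in LK2 the transcription factor genes TWIST1 (-0.30 in H520, 1.58 in LK2) and SNAI2 (0.19 and 1.28) stood out with CCN1 (-0.32 and 1.32) and TGFBI (-0.32 and 0.87). Growth factor receptors had medians of 0.00 and 0.08 (adjusted p = 0.268), and IGFBP3, FGFBP1, DUSP6 and EPHA2 (0.63 and 0.41) led the list. The Notch pathway had medians of 0.12 and 0.11 (adjusted p = 0.241), with JAG1 at 0.22 and 1.81, HES5 at 0.00 and -1.84, HES2 at 0.73 and 0.60 and HES1 at 0.41 and -0.36. NF-kB and cytokines had medians of 0.00 and 0.10 (adjusted p = 0.344), with CXCL8 at 0.76 and 1.13, ICAM1 at -0.28 and -0.39, CXCL1 at 0.22 and 0.37 and NFKBIA at 0.31 and 0.24. Interferon response genes had medians of -0.07 and 0.00 (adjusted p = 0.172), with IFI27 at -0.60 and -1.76, OAS3 at -0.23 and -0.75, MX1 at -0.62 and -0.26 and IFI6 at -0.62 and 0.00.

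Apoptosis regulators had medians of -0.01 in H520 and 0.01 in LK2 (camera adjusted p = 0.999), with BNIP3L at -0.93 and -0.49, HRK at 0.39 and 0.74, BNIP3 as above and TNFRSF10A at 0.33 and 0.31. The median of that list over both lines was 0.04 while its mean was -0.01 and camera's direction down. Unfolded protein response genes had medians of -0.15 and 0.18 (adjusted p = 0.667), with TRIB3 at 0.14 and 1.5, DDIT3 at -0.19 and 0.90, ASNS at -0.34 and 0.74 and SESN2 as above. Ribosomal proteins had medians of -0.02 and -0.07 (adjusted p = 0.249), with RPL7A at 0.43 and -0.49, RPS2 at -0.22 and -0.26, RPS3 at -0.11 and -0.25 and RPS9 at 0.10 and -0.24. Adjusted over the list alone, CXCL8, HES2, FGFBP1 and EPHA2 were called in their lists, and BNIP3L, HRK and BNIP3 among apoptosis regulators. The remaining lists of these 2 paragraphs had 0 such members, and none had a member called over all genes.

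**Figure D3:**
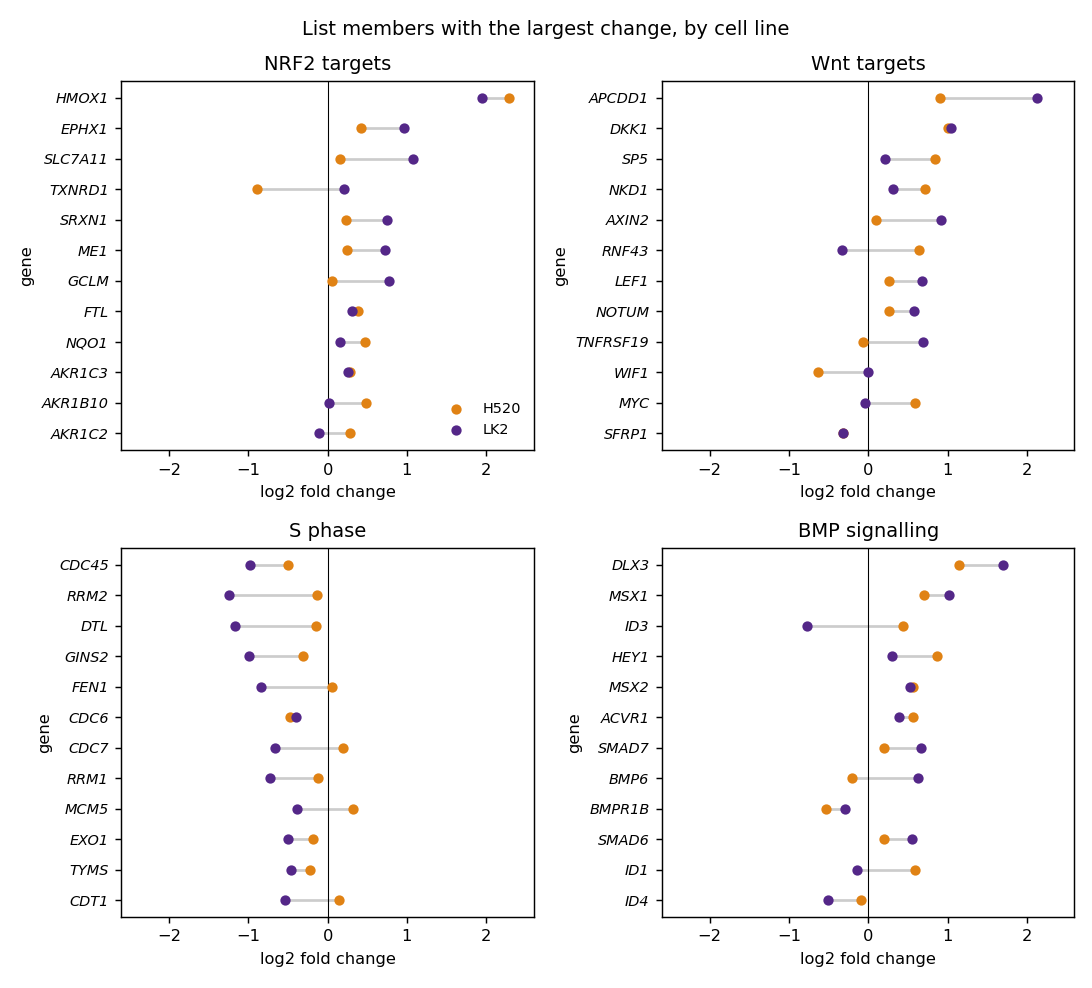
Log2 fold change (SOX2 siRNA over control siRNA) in H520 (orange) and LK2 (purple) of the 12 members with the largest summed absolute change in each of 4 lists, 1 array pair per line. HMOX1 stands at 2.28 and 1.95, and RRM2 at -0.14 and -1.24.

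The lines differed from each other far more than treated from control arrays did. At the adjusted threshold, 2638 genes were higher in LK2 and 2522 higher in H520, with siRNA as a block. The matrix protein gene TGFBI was higher in LK2 by 6.56 ± 0.26 on the log2 scale, SHISA2 by 6.10 ± 0.17, BASP1 by 5.29 ± 0.11 and MOXD1 by 5.18 ± 0.11. ISM1 (5.03), the gap junction gene GJA1 (4.99), SEMA6A (4.97), the Wnt regulator DKK2 (4.87), PCDHB5 (4.47) and NKD2 (4.36) followed. Higher in H520, as LK2 minus H520, were the cancer-testis antigen gene MAGEA4 at -5.55 ± 0.10, ALDH7A1 at -5.51 ± 0.10, PHLDA1 at -5.08 ± 0.12 and S100A6 at -4.72 ± 0.10. ZBED2 (-4.72), MATN3 (-4.65), C6orf15 (-4.65), the interferon-induced IFI27 (-4.53), HTATIP2 (-4.51) and NMRAL1 (-4.47) completed the named genes. SOX2 was at -0.87 ± 0.31 (adjusted p = 0.0911), which averages its control arrays (0.28 in H520 and 0.14 in LK2) with its SOX2 siRNA arrays (-0.38 and -1.97). With a required fold of 1.2, 1459 genes were higher in LK2 and 1357 in H520.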

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

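The genes and the list here were picked because the lines moved in opposite directions, and the noise tests were chosen after those values were seen. With 1 array per group the differences between the lines were not tested. As LK2 minus H520 in log2 change, IGFBP3 differed by 3.11, WIPI1 by 2.27, MT2A by 1.93, EXOG by 1.73, ULBP1 by 1.59 and MT1G by 1.40. ULBP1, at -0.66 in H520 and 0.93 in LK2, lies outside the rule for named genes. CEMIP differed by -2.18, ERVMER34-1 by -1.47 and DUSP6 by -1.29. Medians of the unfolded protein response list differed by 0.33, from the 0.18th percentile of matched random lists in H520 to the 99.92nd in LK2.

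Probe noise was weighed for the genes at least 1.5-fold apart from control in opposite directions, with noise taken from the probe differences of 3934 genes with 2 probes. Over the 6131 genes with more than 1 probe, noise in at least one line would give 0.333 such genes, where IGFBP3 and DUSP6 were seen (exact Poisson p = 0.0445, and 0.0806 at the upper end of 0.468 of that number), and over the 12721 genes with 1 probe it would give 4.19, where 7 were seen (exact Poisson p = 0.131). The probes of IGFBP3 were at -1.40 and -1.59 in H520 and 1.91 and 1.32 in LK2. In either line, 0 of the 3934 genes had noise as large as its change. The 2 probes of DUSP6 also shared a sign within each line, at 0.50 and 0.75 in H520 and -0.52 and -0.81 in LK2. Among the 8 genes other than IGFBP3, noise may account for some and cannot be told apart from a response that differs by line. These tests replaced earlier ones, on probe signs and on counts against independent lists, after those had been seen. A difference between the arrays other than the siRNA stays open for all 9, and the cell line, the biological difference the design names, was not tested.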

How the results depend on the processing

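The probe with the largest line difference, array medians set to 0, genes above the median line difference, and separate probes were chosen after seeing the data. Of 409 fold changes, list medians and correlations compared with the main setting, 0 changed sign, but most of them could not. The variance trend, minimum fold and absent block left fold changes as they were, and the limit on line difference kept the same gene values. Array medians were near 0 already, so the count says little of robustness. By separate probes, 10 of the 37 named genes with more than 1 probe had a probe of the other sign in a line. Shared calls, 1 gene higher and 0 lower in the main setting, were 20 higher and 22 lower with the probe of largest line difference, where SOX2 in LK2 was at -1.89. They were 10 higher and 12 lower with a variance trend, and all 22 of these had a limma adjusted p under 0.1 in the main setting. The values are centred per probe, so that trend runs over a centred mean and not over signal level. Genes above the median line difference gave 0 higher, with HMOX1 at an adjusted p of 0.0726, and no replicate block gave 0 higher, with HMOX1 at 1. Over all alternatives HMOX1's adjusted p ranged from 0.00024, with separate probes, to 1. Of the 25 genes named for the shared response, 17 passed with the trend, 22 with the probe of largest line difference and 1 with array medians at 0 or a minimum fold of 1.2. Separate probes gave 93 higher and 84 lower, 4572 higher in LK2 and 4812 in H520, 155 same-way and 17 opposite probes, 650 in H520 and 1186 in LK2, and r = 0.181. A minimum fold of 1.2 left 1459 genes higher in LK2 and 1357 in H520. Lists past the threshold numbered 0 with an estimated correlation, where 1 residual degree of freedom left hardly any list able to pass. They numbered 0 with fry, also on 1 residual degree of freedom, and 6 with no replicate block. At 2-fold there were 18 same-way and 2 opposite genes, 70 in H520 and 146 in LK2, fewer by construction. Each line alone gave 353 to 604 genes, while 83 moved the same way in both, a part of each count and fewer by construction. For the other moved counts the cause was not tested. Background correction, normalization, offset, detection filters and slide were not run, since they need scanner values assigned to samples, and how far signals lay above background was not examined.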

Other observations

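Between the lines themselves, 6 of the fixed lists passed camera's threshold at the preset correlation, in a test over all 4 arrays that was added after seeing the data. With an estimated correlation all 6 lost the call, each at an adjusted p = 0.909, in a test on 1 residual degree of freedom that hardly any list can pass. BMP signalling genes were higher in LK2 as a list (camera adjusted p = 5.83e-06), with 17 of 28 measured members called higher in LK2 and 1, DLX3, called higher in H520. MSX2 was higher in LK2 by 2.57 ± 0.10 on the log2 scale, HEY1 by 2.55 ± 0.15 and MSX1 by 2.44 ± 0.12. Notch pathway genes were higher in LK2 too (adjusted p = 0.0139), among them HES5 by 3.90 ± 0.38, HEY2 by 3.06 ± 0.13 and NOTCH3 by 2.10 ± 0.10. Targets of p53 (adjusted p = 0.000332) and Wnt targets (adjusted p = 0.0377) went the same way, with CDKN1A at 3.11 ± 0.20 and LEF1 at 1.61 ± 0.13, although GDF15 was at -3.55 ± 0.21 and WIF1 at -1.95 ± 0.16. G2/M genes (adjusted p = 2.14e-07) and S phase genes (adjusted p = 0.00334) were higher in H520, with 22 of 30 and 11 of 27 members called, TPX2 at -2.07 ± 0.11 and GINS2 at -3.39 ± 0.17. All 6 line differences average the control and SOX2 siRNA arrays, so an unequal siRNA response enters them. For S phase genes the median line difference was -0.39, and the siRNA changes had medians of -0.39 in LK2 and -0.01 in H520. For G2/M genes it was -0.59, with siRNA medians of -0.30 and -0.06. Lists were not tested on the control arrays alone. Among probes with no gene name or several, 10 were at least 1.5-fold higher in both lines, 5 lower and 1 opposite.

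The tests on NRF2 targets and S phase genes were all chosen after the results were seen, and the bootstrap test on S phase genes replaced an earlier one on their interquartile range. A candidate explanation for the higher NRF2 list is HMOX1 alone, but the 20 members without it had medians of 0.19 in H520 and 0.15 in LK2 and a camera p of 2.86e-06. Probes shared between paralogs were weighed through the AKR1 genes, and without them the list of 17 had a camera p of 5.38e-07. Both p-values use the preset correlation, with which the list was called. The call did not hold with an estimated one, in a test on 1 residual degree of freedom that hardly any list can pass. The estimated correlation of this list was -0.048, below the preset, so that loss does not show correlation among its members. Glycolysis and hypoxia (-0.027) and BMP signalling (-0.032) also lay below it. The other called lists lay above it: S phase (0.59), G2/M (0.43), Wnt targets (0.18), p53 targets (0.091) and cholesterol synthesis (0.029). For those, p-values at the preset may be too small, though each estimate rests on 1 residual degree of freedom. Neither test bears on a difference between the cultures other than the siRNA, or on other effects of the siRNA pool, and no biological explanation was tested.

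S phase genes were lower in LK2 and had a median near 0 in H520, and one scale factor between the lines, as a deeper knockdown in LK2 might give, was set against this. The H520 median had a 95% bootstrap interval of -0.14 to 0.07, which holds 0, so a ratio of medians has no defined size for this list. Among the other 7 called lists, the ratio of the LK2 to the H520 median ran from 0.27 (BMP signalling) and 0.83 (NRF2 targets) to 4.76 (G2/M). These ratios have no measured spread. LK2 changes were divided by 4.76, the ratio most lenient to a scale factor, and smaller ratios were not tried. The H520 changes of the 27 members then lay above by a median of 0.0895, with an interval of -0.04 to 0.13. That interval holds 0 and treats members as independent. For these 27 genes a factor of that size therefore cannot be told apart from a response of LK2. As one factor for all genes, 4.76 is argued against by HMOX1 (2.28 in H520 and 1.95 in LK2) and SOX21 (-1.66 and -1.21). Both moved more in H520, while others named for changing in both lines, such as KRT23 (1.85 and 2.96), moved more in LK2. A difference between the 2 LK2 arrays other than the siRNA, such as culture density, also stays open, with 1 LK2 array pair.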
